A study of Mus musculus with 4 samples.

How the data were processed

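The series holds 4 single-cell RNA libraries from mice, made with the 10x Chromium 3-prime chemistry per the labels' protocols. RPR2 and CRPR2 were lung tumours of small cell lung cancer, a neuroendocrine carcinoma, and the labels do not spell out either name. The libraries labelled preSC_WT and preSC_CracdKO were tumours grown from preSC cells, a mouse cell line, as allografts, and the labels give their genotypes as WT and CracdKO. Per the labels' protocols, tissue was minced, digested with collagenase, elastase and DNase, cleared of red cells by lysis, passed through a coarse and then a fine strainer and depleted of dead cells before loading. Each group held 1 library, so no spread between animals was measured and no p-value was computed.

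The deposited matrices held whole-number UMI counts per gene and barcode, not normalized by the authors. Per the file headers, the matrices were written by Cell Ranger 6.1.2 for the lung tumours and by Cell Ranger 5.0.0 for the allografts. The submitters' processing notes name Cell Ranger 6.1.2, Scanpy 1.8.2, Seurat with the version 1.8.2, and the mouse build mm10 for every library. The annotation release, the rule for calling cells and any later filter are not given in the sources used here. Each lung matrix listed 32285 features and each allograft matrix 31053, of which 30406 identifiers were in both. The smallest barcode totals were 500 UMIs in RPR2, 501 in CRPR2, 500 in preSC_WT and 500 in preSC_CracdKO. Gene positions were taken from the GENCODE annotation of the same build, which was not necessarily the release used for counting.

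Cells with at least 300 detected genes and at most 15% mitochondrial UMIs were kept. Doublets were called with Scrublet in scanpy 1.11.5 on each library, and where its automatic threshold marked under 0.5% of cells the highest scores were removed at 0.8% per 1000 barcodes. The automatic threshold marked 271 cells (2.97%) in RPR2, 539 (2.92%) in preSC_WT and 887 (5.50%) in preSC_CracdKO, whereas in CRPR2 the fallback removed 1125 cells (9.40%). This left 8857, 10837, 17929 and 15250 cells in RPR2, CRPR2, preSC_WT and preSC_CracdKO. Both libraries of a pair were clustered together on log-normalised counts, 2000 variable genes, 50 principal components, 15 neighbours and Leiden resolution 1.0, with no batch integration, which gave 25 clusters in the lung tumours and 23 in the allografts. The tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16. Random steps used the seed 1.

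Cell types were named from marker genes fixed before the data were examined. The scoring rule itself was set after the clusters were seen and was revised several times. In its final form a cluster took the non-tumour name with the highest mean log2 ratio of markers against the median cluster, with 5 CPM added. Clusters with no such name were scored for the tumour class against the median of the clusters already named. A name needed a score of at least 2, or 0.5 for the tumour class, and at least 3 markers with a log2 ratio of 1 or more that were seen in 20% of cells, or 5% for the tumour class. The tumour score was lowered because tumour clusters of preSC_CracdKO stayed unnamed when doublets were kept. Names were refused where the leading 10 genes at 50 CPM or more held more markers of another class, or where the median depth was below the library's median divided by 3 with no own marker among them. Haemoglobin genes were left out of the leading genes. The clusters left unnamed were cluster 24 of the lung tumours, with 0.0113% of RPR2 and 4.59% of CRPR2 cells, and clusters 3 and 10 of the allografts, with 1.42% of preSC_WT and 0.0393% of preSC_CracdKO cells. Classes named in this way are rebuilt from these data and are called "-like", and the tumour class means cells of neuroendocrine tumour clusters.

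Raw counts were summed over the cells of a class in each library and expressed as CPM, which scales the UMIs of a gene to all UMIs of the class, and log2 ratios of CRPR2 over RPR2 or of preSC_CracdKO over preSC_WT were taken after adding 1 CPM. Sums carry exact Poisson intervals, ratios of sums exact conditional binomial intervals, and shares of cells exact Clopper-Pearson intervals, all at 95% and all covering counting error only. Ratios of shares carry approximate 95% intervals from the standard error of the log ratio, which also cover counting error only and are rougher where few cells were counted. A gene was counted as different at a ratio of 2 or more in either direction with at least 20 CPM in the higher library. For each of 29 gene lists fixed before the data were examined, the median log2 ratio over members with at least 5 CPM in the higher library was set among 10000 random lists of the same size matched on mean expression. The resulting percentile describes these libraries and is not a test. Members of a list were counted as higher or lower at a ratio of 1.5 or more, and a list with under 3 measured members has no median. Immune classes were compared only with at least 50 cells in each library of the pair. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, with shallower cells left out. For a count of 0 the floor was 3 counts of the library's class. In the neuroendocrine list, 19 of the 25 genes also served as naming markers, as did 1 of the lineage factors and 2 of the neuronal genes.

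Named genes followed a rule fixed beforehand, and a pair of the genes it covers are not reported here on their own. They were Cracd, Rb1, Trp53 and Rbl2, the 12 highest and 12 lowest log2 ratios of the tumour class at 50 CPM or more in the higher library, up to 4 members of each described list, 9 genes of MHC class I presentation, Ezh2, Suz12 and Eed, the 6 highest and 6 lowest ratios of T-cell-like and macrophage-like cells at 100 CPM or more, and genes at 2-fold or more the same way in both models. Markers of other classes, haemoglobin, immunoglobulin, mitochondrial and ribosomal protein genes and predicted gene models were left out of the ranked genes. Genes named outside this rule, such as those of the thymocyte panel and of single clusters, were chosen after the data were seen.

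The steps were tested on simulated counts drawn from the tumour-class levels of RPR2 or preSC_WT at the library sizes of each pair, with genes changed by known folds. In the lung simulation 0 of 50 genes changed by 1.5-fold and 50 of 50 at each of 3-, 5- and 10-fold were called among 7003 genes. In the allograft simulation 0 of 50 genes changed by 1.5-fold, 49 of 50 at 3-fold, 49 of 50 at 5-fold and 50 of 50 at 10-fold were called among 7466 genes. No unchanged gene was called in either (0 and 0). These draws held counting error only, with no variation between animals, cells or preparations. They cannot tell how often a gene differs by 2-fold between single libraries for such reasons. A simulated list of 20 raised genes had a median log2 ratio of 1.88 at percentile 100 in both models, and a list of 20 unchanged genes had -0.06 at percentile 22.5 in the lung model and -0.04 at percentile 30.2 in the allograft model.

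The alternatives fixed before the data were examined were no doublet removal, a filter of at least 1000 genes and at most 10% mitochondrial UMIs, Leiden resolution 0.5, separate clustering of each library, scaling by the trimmed mean of M values (TMM) in edgeR, the mean over cells of each cell's CPM, cells thinned to 1000 UMIs, 0.1 or 5 CPM added, a minimum of 100 CPM or none, unthinned cells or cells thinned to 2000 UMIs, and whole libraries in place of the tumour class for the comparison of the models. Chosen after seeing the data were the lung tumours without T-cell-like clusters in which at least 20% of cells held a Rag1, Dntt or Ptcra UMI, without T-cell-like clusters held to 90% or more by 1 library, with each tumour cluster given the same weight in both libraries, and the allografts without clusters 6 and 8. The weighting used only tumour clusters with at least 50 cells in each library, which left out cluster 10. Macrophage-like cells of the allografts were not compared, because 719 stood against 45.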

Results

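RNA of single cells was measured in 4 mouse libraries that form 2 pairs with 1 library per group. RPR2 and CRPR2 were lung tumours of models in which tumours were started by gene deletion. RPR2 is known in this field as loss of Rb1, Trp53 and Rbl2, and CRPR2 as the same with loss of Cracd, although the labels do not spell this out. Tumours grown from preSC cells, a precancerous mouse neuroendocrine line, formed the other pair, labelled preSC_WT and preSC_CracdKO. Both pairs ask how tumour cells and the cells around them differ where Cracd, a regulator of actin capping, is lost. RPR2 held 9215 barcodes with 42592323 UMIs and a median of 2873 per barcode, and CRPR2 held 12164 barcodes with 61917754 UMIs and a median of 3300.5. The library labelled preSC_WT held 18559 barcodes, 93376185 UMIs and a median of 4023, against 16282 barcodes, 110576113 UMIs and a median of 5996 in the library labelled preSC_CracdKO. Differences below are between single libraries, with no replicate check, and all intervals cover counting error only.

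Cracd RNA was lower in CRPR2 than in RPR2 but far higher in the library labelled preSC_CracdKO than in the library labelled preSC_WT. Cracd is listed under its older symbol C530008M17Rik (ENSMUSG00000036377) and lies on chromosome 5 from 76656512 to 76873554 of mm10. In lung tumour cells it stood at 31.6 CPM (29.3 to 34.0, 705 UMIs) in RPR2 and 23.7 CPM (21.9 to 25.6, 634 UMIs) in CRPR2, a ratio of 0.749 (0.671 to 0.834). Allograft tumour cells held 6.38 CPM (5.84 to 6.96, 506 UMIs) in the library labelled preSC_WT and 85.8 CPM (83.9 to 87.6, 8411 UMIs) in that labelled preSC_CracdKO, a ratio of 13.4 (12.3 to 14.7). The allograft level therefore goes against the label, and every direction given for the allografts carries this limit. A 3-prime tag outside a deleted part checks nothing, and RNA of a frame-shifted gene can still be counted.

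In immune cells, Cracd stood at 1.53 CPM in RPR2 and 2.96 in CRPR2, and at 1.45 CPM in preSC_WT and 27.8 CPM (14 UMIs) in preSC_CracdKO. Of those 14 UMIs, 10 lay in the 77 neutrophil-like cells, at 72.7 CPM (34.9 to 134) and a median depth of 942 UMIs. Free tumour RNA in these cells was not tested. The tumour clusters of the library labelled preSC_WT were not alike, with 62.1 CPM in cluster 6 (570 cells), 42.4 CPM in cluster 8 (845 cells), and 2.06, 2.85, 3.46 and 1.87 CPM in clusters 0, 1, 2 and 5. Rb1, the retinoblastoma gene, stood at 121 and 122 CPM in RPR2 and CRPR2 and at 191 and 88.2 CPM in preSC_WT and preSC_CracdKO. Trp53, which encodes p53, stood at 51.7 and 53.4 CPM in the lung pair and at 63.8 and 49.3 CPM in the allografts. For Rbl2, a relative of Rb1, the values were 11.9 and 11.3 CPM in the lung pair and 15.9 and 17.3 CPM in the allografts.

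**Figure D1:**
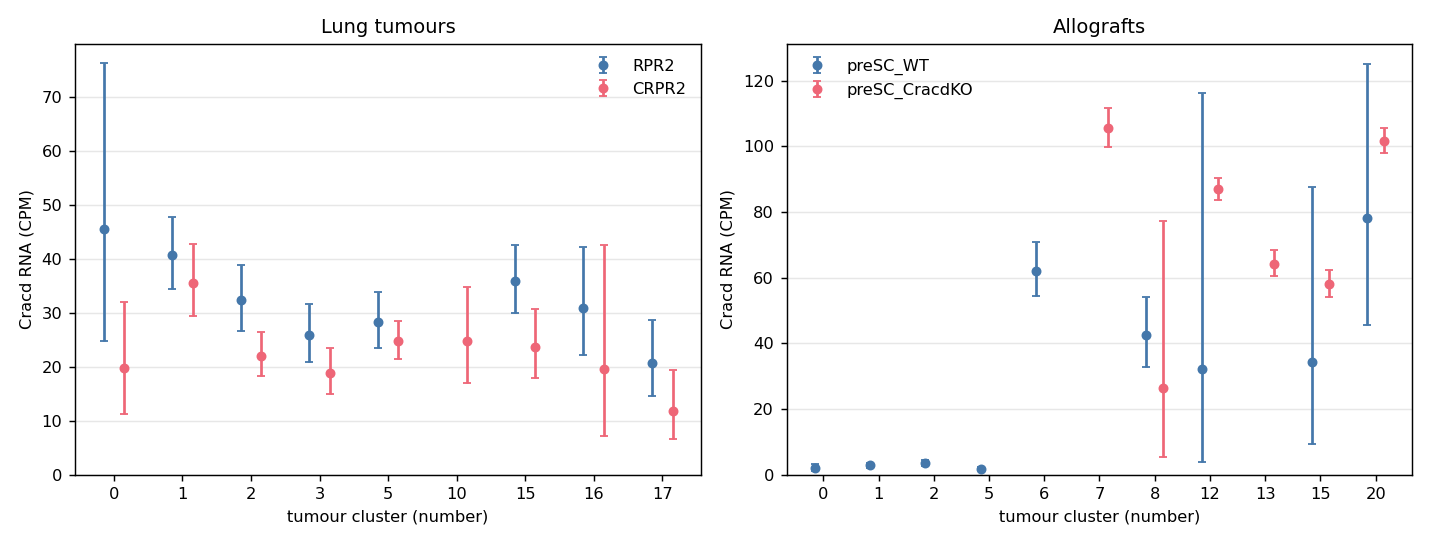
Cracd CPM (linear axis) in each tumour cluster of each library, with exact 95% Poisson intervals as bars. In the library labelled preSC_WT, clusters 6 and 8 stand at 62.1 and 42.4 CPM.

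Among lung cells, RPR2 held more T-cell-like cells, and shares of the other classes depended on these. T-cell-like cells made up 85.8% (84.8 to 86.7) of immune cells in RPR2 and 36.8% (34.9 to 38.8) in CRPR2. Immune cells were 61.8% (60.8 to 62.9) of all cells in RPR2 and 22.1% (21.4 to 22.9) in CRPR2, and tumour cells 34.5% (33.5 to 35.5) and 61.0% (60.0 to 61.9). B-cell-like cells were 7.14% and 31.7% of immune cells, macrophage-like cells 1.31% and 10.0%, and club-like cells, the secretory cells of the airway, 3.16% and 10.9% of all cells. Without the T-cell-like clusters held to 90% or more by 1 library, a choice made after seeing the data, tumour cells were 64.4% (63.0 to 65.7) and 61.0% (60.1 to 61.9) of all cells, and B-cell-like cells 28.7% (26.3 to 31.2) and 31.8% (29.96 to 33.7) and macrophage-like cells 5.29% (4.16 to 6.62) and 10.1% (8.90 to 11.4) of immune cells. Of all cells, NK-like cells were 0.395% and 0.987%, monocyte-like 1.95% and 1.45%, plasma-cell-like 0.779% and 1.36%, neutrophil-like 0.350% and 0.720%, mast-cell-like 0.0903% and 0.221%, fibroblast-like 0.508% and 1.32%, and endothelial-like 0.0226% and 0.120%. These smaller classes were not taken without the T-cell-like clusters held by 1 library, so their differences can come from the larger total of RPR2. Strainers, removal of dead cells and lysis of red cells come before these shares, and median depth was 2786 UMIs in RPR2 and 3148 in CRPR2.

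Most T-cell-like cells of RPR2 lay in clusters that CRPR2 hardly held and that had RNA of genes used by developing thymocytes. Clusters 7, 13 and 14 held 2711, 595 and 90 cells of RPR2 and 0, 0 and 0 of CRPR2, and 88.7%, 96.1% and 94.4% of their cells had a UMI of Rag1, Dntt or Ptcra, which act in assembly of the T-cell receptor. Cluster 11 held 720 cells of RPR2 and 8 of CRPR2, with such a UMI in 6.87% of cells, and cluster 9 held 582 and 876 cells, with 1.03%. Without clusters 7, 11, 13 and 14, each held to 90% or more by 1 library, immune cells were 28.7% (27.4 to 30.0) and 22.1% of cells, and T-cell-like cells 42.8% (40.1 to 45.4) and 36.6% (34.7 to 38.6) of immune cells. T-cell-like cells with a Cd8a or Cd8b1 UMI were 64.9% of immune cells in RPR2 and 8.504% in CRPR2, and 55.9% (54.5 to 57.3) and 6.48% (5.48 to 7.60) after thinning to 1000 UMIs, a ratio of 0.116 (0.0986 to 0.136). Without those 4 clusters this ratio was 0.815 (0.638 to 1.04). They were chosen by their library share, so leaving them out narrows the gap between the libraries by construction. Leaving out only clusters 7, 13 and 14, and so keeping cluster 11, left a larger gap in immune, T-cell-like and Cd8 shares, with the ratios given below under processing. Among B-cell-like cells, which should lack Cd8, the shares were 0.260% and 0.290%, at median depths of 2294 and 1371 UMIs.

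**Figure D2:**
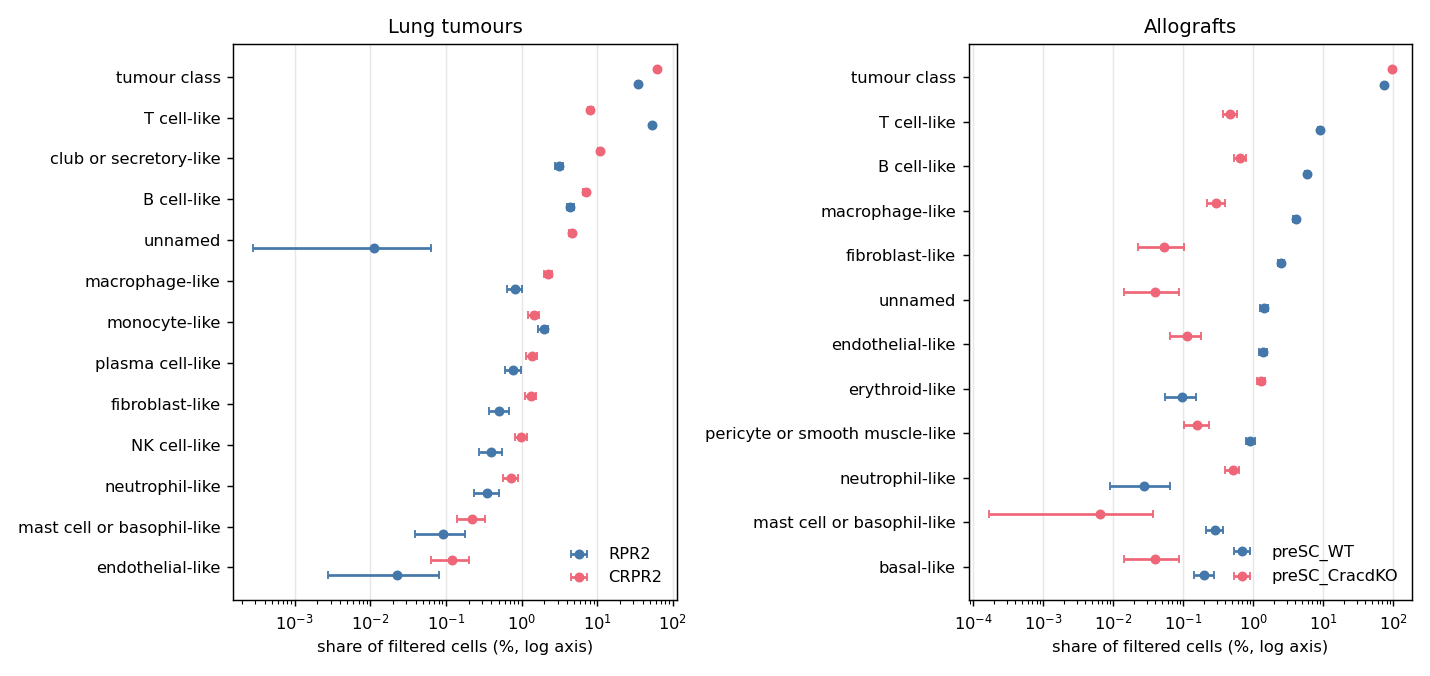
Share of filtered cells (%, log axis) of each cell class in each library of both models, with exact 95% Clopper-Pearson intervals as bars. T-cell-like cells stand at 53.04% in RPR2 and 8.16% in CRPR2.

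Over all T-cell-like cells, effector genes were higher in CRPR2, whereas in cluster 9, the T-cell-like cluster that both libraries held, they were lower. The median log2 ratio of the effector list was 1.31 over all T-cell-like cells, with 12 of 15 members higher by 1.5-fold or more, and -0.84 in cluster 9, with 9 of 15 lower. For the exhaustion list these medians were 1.09 (8 of 12 higher) and -0.81 (8 of 13 lower), and for the regulatory list 1.43 (7 of 9 higher) and -0.05. The list of naive and memory genes stood at 0.48 and 0.04. Percentiles among random lists were 100 for effector, exhaustion and regulatory genes and 99.7 for naive genes over all T-cell-like cells, and 0, 0, 69.8 and 95.5 in cluster 9. The dissociation and stress list stood at -0.24 in cluster 9 (percentile 0.54, 3 of 20 lower and 17 within 1.5-fold), with Nr4a1 at 252 and 135 CPM and Fosb at 278 and 170.3 CPM. The comparison in cluster 9 was chosen after the data were seen.

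In cluster 9, the chemokine genes Ccl3 and Ccl4 stood at 135 and 312 CPM in RPR2 and at 24.3 and 73.3 CPM in CRPR2, 5.56-fold (4.01 to 7.88) and 4.26-fold lower. Gzmb, a granule protease of killer cells, stood at 65.2 and 20.3 CPM, Ifng at 188 and 89.7 CPM, and the inhibitory receptor gene Lag3 at 41.4 and 8.46 CPM, whereas Gzma stood at 125 and 140.4 CPM. Over all T-cell-like cells, Cxcr3 stood at 8.58 and 48.7 CPM, Nkg7 at 99.9 and 345 CPM and Foxp3, the factor of regulatory T cells, at 2.72 and 20.1 CPM, while Satb1 (964 and 286 CPM) and Tox (84.2 and 35.8 CPM) were lower in CRPR2. In cluster 9 these stood at 53.6 and 49.1 CPM for Cxcr3, 534 and 348 for Nkg7 and 12.2 and 20.3 for Foxp3. Satb1 stood there at 259 and 280 CPM and Tox at 68.5 and 36.1 CPM. Of 1585 genes over all T-cell-like cells, 111 were at least 2-fold higher and 340 at least 2-fold lower in CRPR2. S100a4 (7.20-fold), S100a6 (6.92-fold), Gimap3 (6.79-fold), Il18r1 (6.71-fold), H2-Q6 (6.69-fold) and H2-Q7 (6.37-fold) led the higher genes. Lowest were Xist (at least 869-fold), Rag1 (at least 327-fold), Endou (at least 249-fold), Dntt (1105-fold, 198 to 43648, 1 UMI in CRPR2), Arpp21 (974-fold, 175 to 38480.2, 1 UMI) and H2-Q1 (803-fold, 144 to 31729, 1 UMI).

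**Figure D3:**
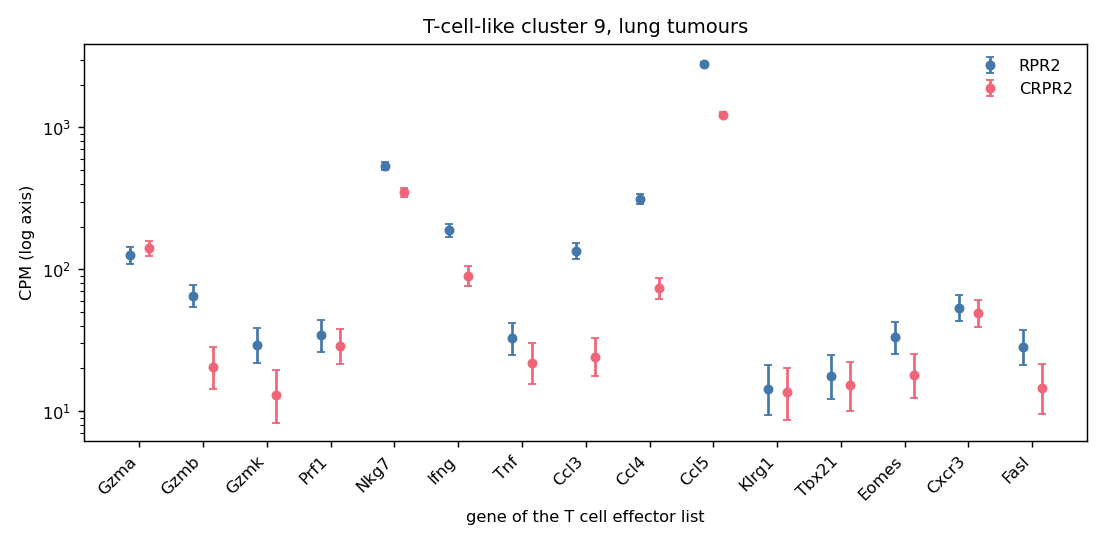
CPM (log axis) of the 15 effector genes in the T-cell-like cluster 9 of the lung tumours, RPR2 and CRPR2, with exact 95% Poisson intervals as bars. Ccl3 stands at 135 CPM in RPR2 and 24.3 CPM in CRPR2, and Gzma at 125 and 140.4 CPM.

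Lung tumour cells of both libraries were alike for most genes, with higher Calca, Anxa5 and S100a11 and lower Id2, Id3 and interferon genes in CRPR2. Of 7204 genes, 37 were at least 2-fold higher and 40 at least 2-fold lower in CRPR2, and the median log2 ratio was -0.03. Calca, which encodes the neuroendocrine peptide precursor of calcitonin, stood at 3473 and 7257 CPM, 2.09-fold higher (2.07 to 2.11). Annexin gene Anxa5 stood at 72.4 and 180.3 CPM (2.49-fold, 2.35 to 2.63) and S100a11 at 71.3 and 176 CPM (2.48-fold, 2.34 to 2.62). The inhibitors of helix-loop-helix factors Id3 and Id2 were lower by 3.74-fold (3.65 to 3.83) and 2.11-fold (2.04 to 2.18).

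Dcpp3 stood at 0.583 and 67.9 CPM, and cluster 10, with 15 cells of RPR2 and 368 of CRPR2, held 1735 of its 1819 UMIs in CRPR2. Also among the 12 highest genes were Obp2a (14.8 and 53.9 CPM), Pianp (34.4 and 92.2 CPM), Acadm, an enzyme of fatty acid oxidation (43.5 and 103 CPM), the hexokinase gene Hk2 (23.5 and 52.1 CPM), Dapk2 (55.3 and 120.6 CPM) and Cartpt (45.3 and 96.6 CPM). The Y-linked genes Eif2s3y and Ddx3y were at 0 UMIs in RPR2 and at 81.4 and 53.9 CPM in CRPR2, at least 605-fold and 401-fold higher. Xist, the RNA of the inactive X chromosome, stood at 1574 and 0.224 CPM, and its antisense partner Tsix at 62.5 and 0.224 CPM. The libraries thus differed in sex-linked RNA as well as in model. Ftl1-ps1, a ferritin pseudogene whose reads can be shared with its parent, stood at 228 and 7.99 CPM, and it was also lower by 55.2-fold in B-cell-like, 38.8-fold in macrophage-like, 42.5-fold in monocyte-like and 47.3-fold in club-like cells. The labels give no strain, and a difference in strain background between the animals was not tested, which limits what the values of Ftl1-ps1 and the H2 genes say about Cracd. Luzp1 (2.73-fold), E2f2 (2.48-fold), Pcp4 (2.28-fold) and Spp1 (2.17-fold) were also lower in CRPR2.

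Type I interferon genes were lower in CRPR2 as a group, with a median log2 ratio of -0.51 at percentile 0 and 8 of 19 measured members lower by 1.5-fold or more and 0 higher. Rsad2 stood at 106 and 30.5 CPM, Isg15 at 110.2 and 35.7 CPM, Oas2 at 8.66 and 3.25 CPM and Rtp4 at 47.4 and 21.2 CPM. Cluster 16, with 163 cells of RPR2 and 55 of CRPR2, held 1177 of the 2373 Rsad2 UMIs and 1108 of the 2457 Isg15 UMIs of RPR2. Within it these genes were not lower in CRPR2, with Rsad2 at 911 and 1167 CPM, Isg15 at 857 and 1112 CPM and Ifit1 at 499.8 and 802 CPM. Ly6e, another interferon-induced gene, was 2.17-fold lower. The interferon gamma list stood at -0.34, also at percentile 0, with 2 of 15 lower, and Igtp at 12.8 and 7.20 CPM. Isg15 had a log2 ratio of -1.76 in B-cell-like and -1.68 in club-like cells of the same libraries, and of -0.27 in monocyte-like and -0.06 in macrophage-like cells.

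MHC class I genes, which present peptides to Cd8 T cells, had a median log2 ratio of -0.06 (percentile 24.7) in lung tumour cells, with 2 of 22 higher and 2 lower. H2-K1 stood at 742 and 658 CPM, H2-D1 at 1881 and 1087 CPM, and B2m at 612 and 489.7 CPM. Among genes of peptide supply, Tap1 stood at 27.8 and 20.6 CPM, Tap2 at 27.4 and 18.9 CPM, Tapbp at 48.9 and 51.7 CPM, Psmb8 at 219.6 and 168 CPM and Psmb9 at 109.9 and 66.0 CPM, and the regulator Nlrc5 at 2.65 and 1.49 CPM. H2-T22 (12.4 and 30.0 CPM) was among the higher members. H2-D1 was lower in other cells of CRPR2 too, with log2 ratios of -0.96 in B-cell-like, -0.88 in macrophage-like, -1.13 in monocyte-like and -1.02 in club-like cells against -0.79 in tumour cells. The MHC class II list stood at -0.06 over 3 measured members.

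Cell cycle lists of CRPR2 tumour cells had medians of -0.53 for the G2 and M phase (9 of 20 lower and 0 higher) and -0.29 for the S phase (0 of 20 beyond 1.5-fold), both at percentile 0. Ube2c stood at 365 and 183.5 CPM and Ccnb1 at 91.7 and 52.3 CPM. With each tumour cluster given the same weight in both libraries, a choice made after seeing the data, the G2 and M phase median was 0.18. This weighting takes out differences in cluster shares, so it cannot tell whether the share of cycling cells differed between the libraries. Neuroendocrine genes stood at 0.13 (percentile 99.8, 3 of 21 higher and 0 lower), with the secretory genes Resp18 at 876 and 1418 CPM and Scg5 at 247 and 378 CPM. The Notch and non-neuroendocrine list stood at 0.37 (percentile 99.96, 2 of 8 higher), with Vim at 1.35 and 6.61 CPM and Cd44 at 10.3 and 21.8 CPM. The unnamed cluster 24, which almost only CRPR2 held, had Vim at 3039.7 CPM and Cd44 at 306 CPM, and free RNA from it was not tested. Because 19 of the 25 neuroendocrine genes served to name the tumour class, cells with little neuroendocrine RNA, such as cluster 24, were left out of it. The tumour-class values of CRPR2 hold for cells outside cluster 24 and do not tell how they would stand with it. Stress genes that respond to tissue dissociation were higher at 0.45 (percentile 100, 6 of 20 higher), with the heat shock gene Hspa1b at 138 and 248 CPM. The stem cell list stood at -0.22 (percentile 0.23, 4 of 13 lower).

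Among lineage factors of small cell lung cancer, the list median was 0.03, with Mycl lower (74.7 and 35.7 CPM) and Nfib lower (382 and 241 CPM). Thinning tumour cells to 1000 UMIs left out 89 and 400 cells. Neurod1 and Pou2f3 had 0 UMIs in thinned tumour cells of both libraries, which allows up to 0.101% and 0.0483% of thinned cells with a UMI and does not limit the cells that express these genes. Yap1 had a UMI in 0.101% and 0.193% of thinned tumour cells, against 0.260% (1 of 384) and 0% (0 of 689) of B-cell-like cells, and in 0.852% and 0.590% of tumour cells unthinned. Median depths were 6048.5 and 3375.5 UMIs in tumour cells and 2294 and 1371 in B-cell-like cells. Among core genes of Polycomb repressive complex 2, which silences genes, Ezh2, Suz12 and Eed were not beyond 1.5-fold, with Ezh2 at 150.1 and 117 CPM, Suz12 at 113 and 101 CPM and Eed at 47.1 and 38.4 CPM, and the list stood at -0.15 (percentile 3.73, 1 of 11 higher and 0 lower).

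Actin and capping genes of lung tumour cells stood at -0.01 (1 of 29 higher and 1 lower), with Capg at 19.1 and 31.8 CPM and Capzb at 175 and 113 CPM. Medians were 0.04 for epithelial-mesenchymal transition, 0.07 for Wnt targets, 0.03 for hypoxia and glycolysis, -0.08 for oxidative phosphorylation, -0.04 for the unfolded protein response, -0.0037 for cholesterol synthesis, -0.05 for p53 targets, 0.02 for checkpoint ligands, -0.13 for chemokines and 0.04 for neuronal genes. Lists of immune genes had few measured members in tumour cells, with medians of -0.43 for T-cell exhaustion (4 members, percentile 0.49), -0.24 for naive genes (4 members, 11.9), 0.65 for regulatory genes (3 members, 99.9), -0.56 for inflammatory (3 members, 0.21) and 0.05 for alternative macrophage genes (6 members, 79.3), and none for T-cell effector genes, of which 2 were measured. RNA of other cells differed as well, with Cd3 and Trac genes at 19.8 and 2.46 CPM, haemoglobin at 1.48 and 599 CPM and club markers at 118 and 687 CPM in tumour cells.

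**Figure D4:**
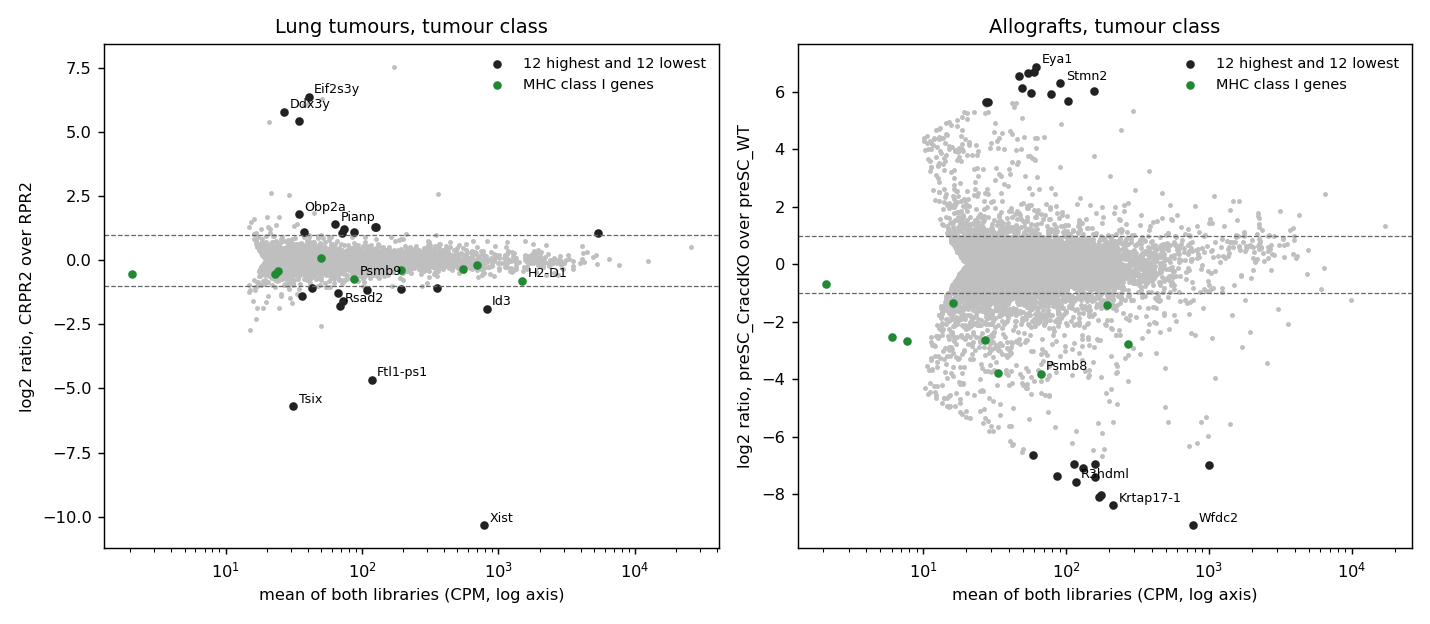
Log2 ratio of each gene in tumour cells (1 CPM added) against its mean CPM (log axis) in both models, with all genes of at least 20 CPM in grey, the 12 highest and 12 lowest in black, MHC class I genes in green and dashed lines at 2-fold. In the lung pair 37 genes lie above and 40 below the dashed lines, and in the allografts 570 and 1162.

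Macrophage-like cells of the lung pair (72 and 241 cells) had higher Arg1 and lower Ccl5 in CRPR2, while each list had members that went both ways. Arg1, an enzyme of alternatively activated macrophages, stood at 43.1 and 437 CPM, 10.1-fold higher in CRPR2 (5.59 to 20.5), while the chemokine gene Ccl5 stood at 459 and 17.6 CPM, 26.1-fold lower (14.7 to 50.4). Ccl24, Sprr1a and Prg4 were at 0 UMIs in RPR2 and at least 31.5-fold, 10.8-fold and 10.7-fold higher, and Ifitm1 was 33.8-fold higher (5.93 to 1350, 1 UMI in RPR2). Lower in CRPR2 were Xist (at least 289-fold), Ftl1-ps1 (38.8-fold), Dusp2 (11.6-fold), Hist1h3c (5.79-fold) and Id1 (5.44-fold). H2-Eb1, a class II gene, stood at 39.2 and 1628 CPM, and it was also higher in CRPR2 by 10.0-fold in B-cell-like, 137-fold in monocyte-like and 21.6-fold in club-like cells. The chemokine list stood at 0.54 (9 of 19 higher and 5 lower), inflammatory genes at 0.39 (5 and 3 of 12), alternative genes at 0.24 (3 and 3 of 11) and class II genes at 0.13 (2 and 1 of 11). With the member at 0 counts set to 3 counts, the chemokine median was 0.52 and the class II median 0.04. Across 1577 genes, 41 were at least 2-fold higher and 50 lower.

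Over whole lung libraries, 247 of 7232 genes were at least 2-fold higher in CRPR2 and 296 lower. Without the T-cell-like clusters held to 90% or more by 1 library, 191 of 7166 were higher and 68 lower, which moved the higher share from 45.5% to 73.7%.

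In the allografts, the library labelled preSC_WT held more immune cells, fibroblast-like and endothelial-like cells, and the library labelled preSC_CracdKO was nearly all tumour cells. Immune cells were 19.1% (18.5 to 19.6) and 1.92% (1.71 to 2.15) of cells and tumour cells 74.4% (73.8 to 75.1) and 96.4% (96.1 to 96.7). T-cell-like cells were 46.9% (45.3 to 48.6) and 24.2% (19.4 to 29.6) of immune cells, B-cell-like cells 30.4% and 33.8%, macrophage-like cells 21.0% and 15.4%, neutrophil-like cells 0.146% and 26.3% and mast-cell-like cells 1.49% and 0.341%. Fibroblast-like cells were 2.51% and 0.0525% of all cells, endothelial-like 1.37% and 0.111%, pericyte-like 0.909% and 0.157%, basal-like 0.201% and 0.0393% and erythroid-like 0.0948% and 1.30%. Cells with Cd8 UMIs were 16.4% and 7.85% of immune cells, and 16.2% (14.6 to 18.0) and 9.22% (5.001 to 15.3) after thinning, against 1.04% and 0% (0 of 20) of B-cell-like cells. The direction depended on the cell filter, since the ratio of the thinned shares was 0.568 (0.335 to 0.963) but 1.23 (0.541 to 2.79) in cells with at least 1000 genes and at most 10% mitochondrial UMIs. The same strainers, dead-cell removal and red-cell lysis apply, at median depths of 3968 and 5897 UMIs.

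T-cell-like cells of the allografts (1604 and 71 cells) had lower effector and higher naive genes in the library labelled preSC_CracdKO. The effector list stood at -1.81 (percentile 0, 12 of 15 lower), or -1.13 with its member of 0 counts set to 3 counts, and the naive list at 0.90 (percentile 100, 8 of 10 higher). Exhaustion genes stood at -0.91 (8 of 13 lower), or -0.85 at that floor, and regulatory genes at -1.15 (8 of 11 lower), or -0.54 with 3 members at the floor. Ccl4 stood at 825 and 31.6 CPM (3 UMIs), 26.1-fold lower (8.93 to 127), Ifng at 356 and 42.1 CPM and Gzmb at 302 and 63.1 CPM, while Lef1 stood at 306 and 915 CPM. Of 1800 genes, 137 were at least 2-fold higher and 319 lower. Hspbap1 (7.49-fold), Cdk8 (6.20-fold), Pik3ip1 (5.89-fold), Igf1r (5.03-fold), Rflnb (4.89-fold) and Fam241a (4.53-fold) were highest. Lowest were Lgals3 (at least 6.23-fold), Ifitm1 (at least 5.27-fold), Wfdc2 (at least 3.67-fold), Ifi213 (at least 3.48-fold), Cd9 (29.3-fold, 5.24 to 1159, 1 UMI) and Ccl4, and Wfdc2 was also among the lowest genes of tumour cells.

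Allograft tumour cells differed far more than lung tumour cells, with Krt8 and Cdh1 lower and Eya1 and Nrg1 higher in the library labelled preSC_CracdKO. Of 8151 genes, 570 were at least 2-fold higher and 1162 lower in preSC_CracdKO, or 660 and 1011 with TMM scaling, which moved the median log2 ratio of all genes from -0.15 to -0.04. Krt8, a keratin of simple epithelia, stood at 1990.4 and 14.7 CPM, 135-fold lower (129 to 143), and Cdh1, which encodes E-cadherin, at 316 and 0.897 CPM, 352-fold lower (286 to 439). Eya1, a transcriptional coactivator of organ development, stood at 0.0631 and 124 CPM, 1959-fold higher (839 to 6033), and the growth factor gene Nrg1 at 3.75 and 311 CPM, 82.9-fold higher (73.9 to 93.3). Tumour cells of preSC_WT lay mostly in clusters 0, 1, 2, 5, 6 and 8 and those of preSC_CracdKO in clusters 7, 12, 13, 15 and 20. By chromosome, the median log2 ratio ran from -0.61 on chromosome 1 (490 genes) to 0.39 on chromosome 15 (344 genes). In the lung pair these medians ran from -0.14 to 0.01. Differences in whole chromosome copies between the allografts were not tested.

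Also highest in preSC_CracdKO were the transcription factor genes Bcl11a (0.151 and 118 CPM), Zfhx4 (0.0883 and 109 CPM), Isl1 (0.0126 and 93.6 CPM, 1 UMI in preSC_WT, 7422-fold, 1332 to 293174), Zfp536 (1.56 and 155 CPM) and Foxr2 (0.101 and 54.8 CPM), with Stmn2 (1.30 and 181 CPM), Pet2 (256-fold), Nyap2 (135-fold), Prkcb (67.9-fold) and Slc24a2 (371-fold). Lowest were Wfdc2 (1539 and 1.87 CPM), Krtap17-1 (1544-fold), the tight junction gene Cldn7 (341 and 0.245 CPM), Anxa1 (171 and 0.0612 CPM), the immediate-early genes Egr3 (1004-fold) and Egr4 (197-fold), R3hdml (993-fold), Thbs1 (274-fold), F5 (264-fold) and Mest (574-fold).

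MHC class I genes were lower together in the library labelled preSC_CracdKO, with a median log2 ratio of -2.49 at percentile 0 and 15 of 21 members lower and 0 higher, or a median of -1.39 with 5 CPM added. H2-D1 stood at 471 and 68.9 CPM, 6.83-fold lower (6.66 to 7.01), H2-K1 at 282 and 104 CPM, 2.70-fold lower (2.64 to 2.76), and B2m at 47.5 and 6.88 CPM, 6.90-fold lower (6.35 to 7.50). Immunoproteasome genes Psmb8 and Psmb9 were 15.5-fold (14.4 to 16.7) and 17.2-fold (15.5 to 19.2) lower. The peptide transporter genes Tap1 and Tap2 stood at 11.03 and 1.08 CPM and at 13.9 and 1.36 CPM, Tapbp stood at 23.4 and 8.64 CPM and Nlrc5 at 2.79 and 1.35 CPM. Type I interferon genes stood at -1.61 (percentile 0.02, 11 of 13 lower), with Bst2 at 18.9 and 0.602 CPM, and interferon gamma genes at -1.15 (7 of 10 lower and 2 higher), with the kinase gene Jak1 higher at 3.39 and 70.5 CPM. Checkpoint ligands stood at -1.08 (4 of 7 lower), with Cd274, which encodes PD-L1, at 8.62 and 3.26 CPM.

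Dissociation and stress genes were lower in the library labelled preSC_CracdKO, with a median of -4.51 and 20 of 20 members lower, among them Fos (2744 and 57.2 CPM), Egr1 (1629 and 21.1 CPM) and Atf3 (1429.9 and 17.1 CPM). Hypoxia and glycolysis genes were higher at 0.85 (percentile 100, 15 of 20 higher and 0 lower), with Hk2 at 1.955 and 34.7 CPM, Pgk1 at 142 and 802 CPM and Ldha at 213 and 601 CPM. Neuroendocrine genes stood at -0.76 (percentile 0.02, 14 of 23 lower and 2 higher), with the prohormone convertase gene Pcsk1 at 486 and 54.6 CPM and Calca at 3252 and 639 CPM. Neuronal genes stood at 0.35 (percentile 99.4, 10 of 21 higher and 6 lower), with Grik2 at 7.32 and 108 CPM and Mapt at 98.2 and 24.9 CPM. Actin and capping genes stood at -0.42 (percentile 1.48, 12 of 29 lower and 1 higher), with Vcl at 229 and 30.9 CPM and Actg1 at 5801 and 1396 CPM.

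Lineage factors of the allografts had a median of -0.52, with Sox2 higher in preSC_CracdKO (4.73 and 119.8 CPM), Nfib higher (156.5 and 514 CPM) and Myc lower (20.1 and 2.69 CPM). Thinning left out 660 and 170 tumour cells. Shares of thinned tumour cells with a UMI were 0.110% and 0.227% for Neurod1, 0.236% and 0.468% for Pou2f3, with 0.347% in B-cell-like cells of preSC_WT, and 0.142% and 0.158% for Yap1. Unthinned, these shares were 1.02% and 1.70%, 1.33% and 2.87%, and 0.592% and 1.48%. Median depths were 4742 and 5963.5 UMIs in tumour cells and 845 and 779 in B-cell-like cells. Ezh2 stood at 148 and 191 CPM, Suz12 at 141 and 142 CPM and Eed at 49.97 and 50.7 CPM, and the Polycomb list had a median of 0.0046.

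Other lists of allograft tumour cells had medians of -1.06 for Notch and non-neuroendocrine genes (4 of 5 lower), -1.26 for Wnt targets (4 of 5 lower), -0.62 for stem cell genes (7 of 14 lower and 2 higher) and 0.07 for epithelial-mesenchymal transition (3 of 8 higher and 3 lower). Lin28b stood at 0.442 and 55.9 CPM and Twist1 at 0.0252 and 25.6 CPM. S phase genes stood at -0.18, G2 and M phase genes at 0.17, oxidative phosphorylation at 0.19, the unfolded protein response at -0.35, cholesterol synthesis at -0.31 and p53 targets at -0.35, with Cdkn1a at 619 and 124 CPM. T-cell exhaustion, naive and regulatory genes stood at -0.33, -0.98 and -0.01 and alternative macrophage genes at -1.77 in tumour cells, while class II, chemokine, effector and inflammatory lists had 1, 2, 1 and 2 measured members. Ribosomal protein genes took 9.96% and 17.4% of tumour-cell UMIs and mitochondrial genes 1.76% and 2.87%. RNA of other cells in tumour cells stood at 154 and 91.9 CPM for macrophage markers, 10.1 and 1.39 CPM for immunoglobulin, 2.21 and 2.36 CPM for Cd3 and Trac genes and 7.52 and 78.5 CPM for haemoglobin. Whole allograft libraries had 566 of 8255 genes higher and 1216 lower, or 766 and 974 with TMM scaling, which moved the higher share from 31.8% to 44.0% and the median log2 ratio from -0.12 to 0.05.

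**Figure D5:**
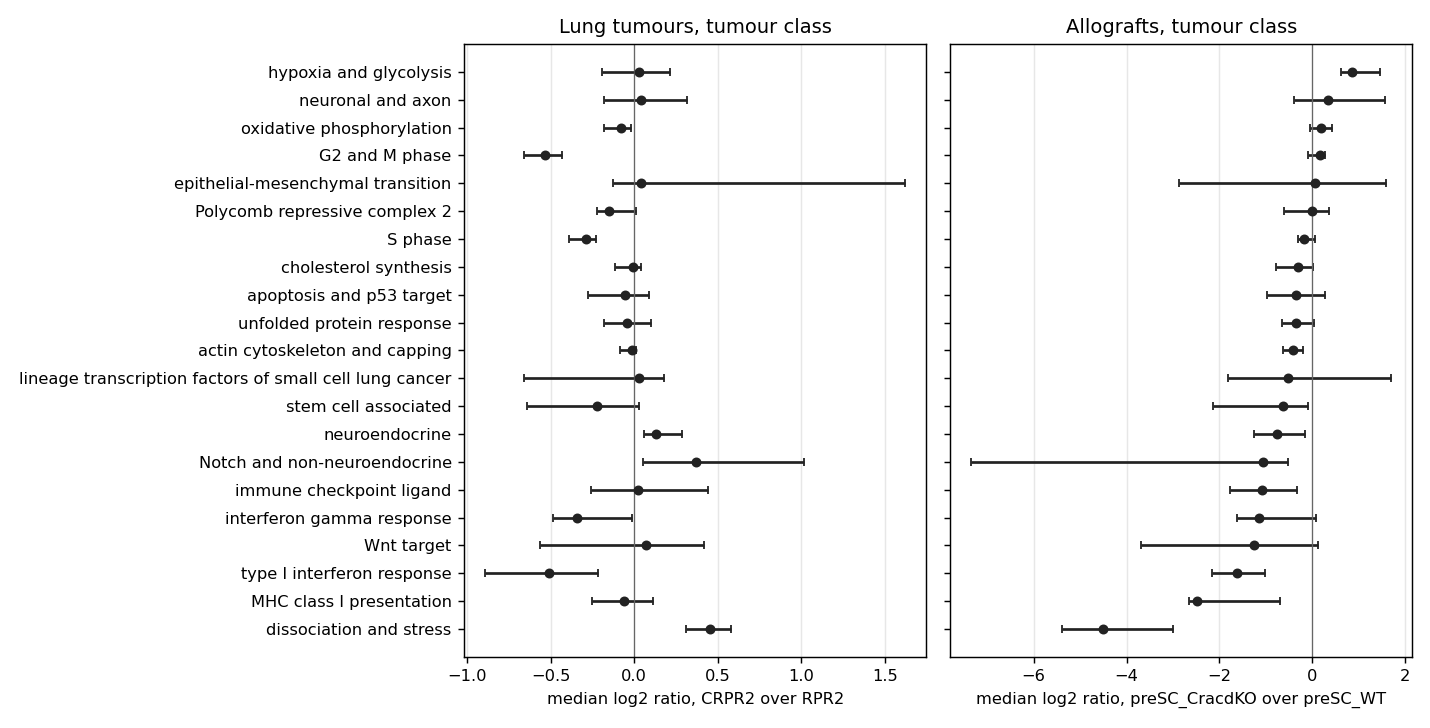
Median log2 ratio of each gene list in tumour cells of both models, for lists with at least 5 measured members in each, with 95% bootstrap intervals over genes as bars. MHC class I genes stand at -0.06 in the lung pair and -2.49 in the allografts, and dissociation genes at 0.45 and -4.51.

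Differences in tumour cells, taken in the direction of the labels, had a negative relation between the models. Over 6535 genes, Pearson r was -0.249 and Spearman rho -0.298, and 42.3% of genes had the same sign, across genes, which are not independent replicates, and the pairs share no library. At 2-fold or more, 3 genes were higher in both (0.413 for independent lists), 4 lower in both (2.59) and 13 opposite (2.35). These signs rest on the allograft labels, which the Cracd RNA goes against. With the allograft ratio turned, r and rho would be positive at the same size, the 13 opposite genes would be shared and the 7 shared genes opposite. Named among these, Anxa5 and Hk2 were higher in both, with Anxa5 at 6.64 and 41.3 CPM in the allografts. Id3 (433 and 128 CPM in the allografts), Rsad2 (31.7 and 12.3 CPM), Pitpnc1 (78.7 and 21.1 CPM) and Chl1 (98.3 and 0.0714 CPM) were lower in both.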

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

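The tests of thymus tissue, free RNA of thymocyte-like cells, swapped labels and a Cracd-rich cell state were chosen after the result was seen, and those of a T-cell clone, copy loss, dissociation and free immune RNA before.

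Several results went opposite ways in the lung pair and the allografts, and these differences between models were not tested. They hold in the direction of the labels, and with the allograft ratio turned each of these opposite pairs of log2 ratios would have the same sign. The neuroendocrine list had a median log2 ratio of 0.13 in the lung pair and -0.76 in the allografts, and the dissociation and stress list 0.45 and -4.51. Cracd had log2 ratios of -0.40 and 3.55. Over all T-cell-like cells the effector list stood at 1.31 and -1.81 and the exhaustion list at 1.09 and -0.91. In the lung cluster 9, which both libraries held, these lists stood at -0.84 and -0.81, the same sign as in the allografts. For cluster 9, turning the allograft ratio would make the signs opposite. Outside the compared classes, the trefoil factor gene Tff1 reached 543.5 CPM in the unnamed cluster 24 of CRPR2, against 0.373 CPM in CRPR2 tumour cells.

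RPR2 held T-cell-like clusters with RNA of a thymocyte panel, with Rag1 at 646 CPM, Dntt at 730.0 CPM and Cd8b1 at 1014 CPM. Free RNA was argued against, since tumour cells of RPR2 held at most 0.569% of these levels. Thymus tissue collected with the tumours may be the source but stays open. All 8 panel genes passed the level set for it. Of cells thinned to 2000 UMIs, 15.5% (13.6 to 17.6) held UMIs of both Cd4 and a Cd8 gene, under the 20% set. Without cluster 11, in which few cells had a UMI of Rag1, Dntt or Ptcra, this share was 21.5% (18.9 to 24.4), which includes that limit. It was 48.5% in cluster 7, 13.96% in cluster 13 and 0% (0 of 90) in cluster 14. Thinning kept 1282 cells and left out 2834, among them 2478 of the 2711 cells of cluster 7. The pooled share thus depends on this depth cut and cannot decide the question. Outgrowth of 1 clone also stays open, since Trbv2 held 24.9% (21.97 to 28.03) of 815 Trbv UMIs over 23 genes, between the limits set. A biological difference between the models was not tested.

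In the allografts, Cracd RNA went against the label. A swap of both labels stays open. Cluster 6 of the library labelled preSC_WT stood at 62.1 CPM against 1.45 CPM in its immune cells. This cannot decide it, because RNA of a frame-shifted gene would allow such a level, and CRPR2 tumour cells also held 23.7 CPM. Cracd RNA may instead go with a cell state, which also stays open. Over 8172 genes, the difference between cluster 6 and tumour cells outside clusters 6 and 8 of that library went with the difference between the libraries at a Pearson r of 0.664, against 0.428 for cluster 8 and -0.140 to 0.371 for 4 other tumour clusters and 4 other cell classes of at least 300 cells. Of the genes higher between the libraries, cluster 6 shared 35.3%, against 22.7% for cluster 8 and 0% to 25.4% for those other groups. Of the genes lower between the libraries, however, cluster 6 shared 52.5% and cluster 8 46.1%, fewer than B-cell-like (70.8%), T-cell-like (70.1%), fibroblast-like (67.1%) and macrophage-like cells (54.6%). The 4 other tumour clusters shared 0.417% to 2.53% of the lower genes. Hypoxia and glycolysis genes were lower in cluster 6 (-0.50) and higher between the libraries (0.85). Cluster 6 was picked for its Cracd RNA. Both differences were taken against tumour cells of the library labelled preSC_WT outside clusters 6 and 8, split at random so that they shared no reference cells. The values of r and the shared genes are relations across genes, and whether Cracd loss itself acts here was not tested.

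MHC class I RNA was lower in the library labelled preSC_CracdKO, at -2.49. Loss of chromosome copies was argued against, since 139 genes of other function within 2 Mb of these loci had a median of -0.14 (-0.33 to -0.04). Free immune RNA was argued against by a highest share of 4.08%, from the median of 10 leukocyte genes, although Coro1a stood apart (53.4 CPM in tumour cells) and would alone allow 20.5% of H2-D1, 32.9% of Psmb8, 21.7% of Psmb9 and 153% of B2m. A different stress response to dissociation could not be settled. Between the lowest-scoring tumour cells of each library the median was -1.86, beyond the -1.5 set against this cause, but its interval (-2.31 to -0.53) reached past that limit, and those cells still differed in score (0.334% and 0.0707% of UMIs). The label's genotype stays open and untested, and goes against the Cracd RNA.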

How the results depend on the processing

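The leaving out of T-cell-like clusters and of clusters 6 and 8, and the equal cluster weights, were chosen after the result was seen. No paired analysis was possible because each group held 1 library. A value was kept where it lay within the interval of the main setting, or for gene counts within 1.5-fold. It was reversed where the direction turned and the main value was at 2-fold or more, for genes, or had an interval that excluded no difference. Other values moved, and shares in single libraries and gene counts could not reverse. For the results that answer a comparison, other settings chosen before the data were seen gave 144 values, of which 118 were kept, 25 moved and 1 reversed. Those chosen later gave 19, of which 10 were kept, 8 moved and 1 reversed. Single genes and other lists gave 1245 values with the former (1062 kept, 183 moved, 0 reversed) and 152 with the latter (107, 42 and 3). Allograft MHC class I medians ranged from -2.75 to -1.39 and lung ones from -0.11 to -0.01. Where gene numbers moved with a CPM limit, fewer or more genes entered by construction, and for other moves the cause was not tested.

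In lung tumour cells, 25 genes were lower with 5 CPM added, 9 higher and 9 lower at 100 CPM or more, and 105 higher and 236 lower with no minimum. Whole lung libraries had 447 higher and 539 lower by the mean of per-cell CPM. Without doublet removal the T-cell-like ratio was 0.367, the Cd8 ratio 0.0725 and the effector median 1.80. With the strict cell filter, ratios were 0.2398 for immune, 0.3495 for T-cell-like and 0.0716 for Cd8 cells. Without clusters with Rag1, Dntt or Ptcra these were 0.581, 0.589 and 0.433, and without clusters held to 90% by 1 library 0.769, 0.857 and 0.815. The latter kept 582 of the 4698 RPR2 T-cell-like cells, gave 68 lower genes and reversed the medians of effector (-0.84), exhaustion (-0.81) and regulatory genes (-0.052). The same cluster weights in both libraries reversed the G2 and M phase median to 0.18, and such weights take out differences in cluster shares by construction.

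In the allografts, the Cracd log2 ratio was 3.36 thinned, 3.73 with 0.1 CPM added, 3.00 with 5 CPM added and 4.49 without clusters 6 and 8, and the MHC class I median was -2.75 with 0.1 CPM added and -1.39 with 5 CPM added. At 100 CPM or more 164 genes were higher and 391 lower, and with no minimum 1519 and 2113. The strict cell filter moved the immune ratio to 0.0893 and reversed the Cd8 ratio to 1.23 (0.541 to 2.79). Between the models, Pearson r was -0.345 at 100 CPM or more, -0.124 with no minimum and -0.162 over whole libraries, all in the direction of the labels, and each would be positive with the allograft ratio turned.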

Other observations

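The descriptions of single clusters below and the tests of focal gains were chosen after the result was seen.

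CRPR2 held a cluster with little neuroendocrine RNA and with RNA of both keratin and mesenchymal genes, which RPR2 hardly held. Cluster 24 had 497 cells, 4.59% (4.1999 to 4.997) of CRPR2, and 1 cell of RPR2. Against CRPR2 tumour cells, all 21 measured neuroendocrine genes were lower (median log2 ratio -5.14), as were 16 of 17 neuronal genes (-4.18), 18 of 22 MHC class I genes (-2.07) and 19 of 20 dissociation and stress genes (-3.08). Whether handling played a part was not tested. Genes of epithelial-mesenchymal transition were higher (4.61, 15 of 17), with those of Notch and the non-neuroendocrine state (2.81, 12 of 15) and of actin (1.13, 22 of 30). The intermediate filament gene Vim stood at 6.61 CPM in tumour cells and 3039.7 CPM in the cluster, Lgals1 at 12.6 and 3658 CPM and Spp1 at 27.1 and 4751 CPM. Within the cluster the keratin genes Krt8 and Krt18 stood at 2306 and 3159.9 CPM, Cdh1 at 107 CPM, Epcam at 179.8 CPM and the collagen gene Col1a1 at 1.80 CPM. Secretogranin gene Scg2 stood at 634 and 9.41 CPM and the chemokine gene Cxcl13 at 1089 and 16.4 CPM. Its median depth was 13329 UMIs against 3148 in CRPR2, so doublets have to be weighed, although neuroendocrine RNA was nearly absent. With almost all cells from 1 library, a cell type of CRPR2 tumours cannot be told from a feature of that animal or preparation, and neither was tested.

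Tumour cells of the library labelled preSC_WT held smaller clusters that differed from the rest. In cluster 6, 17 of 21 MHC class I genes were lower than in the other tumour cells (-1.28), as were type I interferon genes (-1.962) and dissociation genes (-3.27). In cluster 8 these medians were -0.58, -0.92 and -2.17.

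A hypothesis is that these clusters carry focal gains of Myc genes. Around Mycn, on chromosome 12 from 12936093 to 12941914, 6 genes within 1 Mb had a median log2 ratio of 2.96 in cluster 6, with Mycn at 5.43 and 89.0 CPM, Ddx1 at 111 and 687 CPM and Nbas at 65.5 and 533 CPM, while 29 genes 5 to 10 Mb away had -0.32. Around Myc, on chromosome 15 from 61985391 to 61990374, 4 genes within 1 Mb had 3.79 in cluster 8, with Myc at 20.0 and 58.4 CPM and Pvt1 at 44.6 and 1274 CPM, and 17 genes farther away had -0.40. Each set included Mycn or Myc itself. The median around Myc was set by AC140304.1 and AC140304.2, gene models at 0.364 and 0.405 CPM in the other tumour cells, near the floor. The values around both genes would go with focal gains, but RNA does not count DNA copies, and shared regulation of neighbours was not tested.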
